A study of Homo sapiens with 35 samples.

How the data were processed

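Total RNA of 12 untreated human colorectal carcinoma lines was hybridised to single-colour Agilent miRNA arrays. Per the labels, RNA came from passages 4 to 6 of each line and 500 ng of it was labelled with Cy3. The 35 arrays were 3 per line, except SW480 with 2. No label ties an array to 1 passage or culture, so p-values measure the spread between the arrays of a line, which may be technical in part. The arrays lay on 5 slides, each scanned once, and no scan differed from its slide.

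The deposited scanner files hold spot intensity values on a linear scale, written by Agilent Feature Extraction 10.7.3.1 per the file headers, while the submitters' processing notes name version 9.1 together with limma. The background-subtracted spot intensity was used here. Each array carried 56044 spots. Of these, 53880 belonged to 3523 miRNA probes with 10 to 40 spots each, covering 1205 human and 142 viral miRNAs with 1 to 4 probes per miRNA. No spot was saturated on any array. A deposited table of 1 value per miRNA and array was used as an alternative. Its scale is not given in the sources used here. Its columns ranked the probes as the median spot signal did (Spearman correlation 1.0) and correlated with the log2 of that signal at 0.996 to 1.00, so the deposited values were read as log2 intensity. The column medians ran from 4.32 to 4.39 and each column had the maximum 15.9, as after quantile normalization. No centring per miRNA was present, and a single-colour value has no direction to settle.

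Control spots and spots marked as outliers were left out, at most 7.79% of the spots of an array. The signal of a probe was the mean over its remaining spots. A probe counted as detected where at least a share of 0.5 of its spots was well above background by the scanner's own call, and a miRNA where at least 1 of its probes was. Each array was divided by the 75th percentile of its human probes that were detected on all arrays, because under a share of 0.5 of the probes were detected. A common floor at log2 -7.01 was then set and log2 taken. A miRNA was represented by its probe of highest mean signal over all arrays. Tested were the 466 human miRNAs detected on every array of at least 1 line. Names are those of the array's design. The 139 miRNAs that the rule for names took all had several probes, whose lowest pairwise correlation over the arrays had a median of 0.988. It was under 0.5 for miR-182, miR-195 and miR-126*, at 0.265, 0.485 and 0.464, and 17 named miRNAs had a probe at the floor on all arrays.

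One linear model with a mean per line was fitted to all 35 arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes without trend), with 23 residual degrees of freedom, 2.67 prior degrees of freedom and a median residual SD of 0.243 log2. The moderated F test asked which miRNAs differed between the 12 lines. Contrasts compared SW620 with SW480, WiDr with HT29, and each line with the mean of the other 11 line means. Each test was adjusted over the 466 miRNAs by the Benjamini-Hochberg method, and an adjusted p under 0.05 is called changed, higher or lower. Gene lists were tested with camera of limma with an inter-gene correlation estimated from the arrays, adjusted over the 30 lists with at least 2 tested members in each pair of lines, and over all 360 line and list tests together for the 12 lines. The preset correlation of 0.01 was the alternative. Since camera sets a list against all other tested miRNAs, its direction is relative to them. That direction can therefore part from the sign of the list's own median or mean. Distances between lines are root mean square differences of line means over the 466 miRNAs, and the mean distance of the 2 related pairs was set against all 1485 choices of 2 disjoint pairs in an exact one-sided test. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 read the files and drew the plots.

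A miRNA that was not well above background on any array of a group has only a bound there. Its ratio is given as at least N-fold, the mean of the brighter group over the mean, per dim array, of the highest of the common floor, the lowest signal among probes well above background and its own signal. Where a line was brighter than the mean of the others and only some of the others were dim, a bound is also given. The dim lines then enter that mean at the raised value and the rest at their measured level. Where a line was lower than the others and some of the others were dim, or the bound was under 1, no fold is given. Values at the floor have no spread, so the limma p-values of miRNAs below background in many lines are too small. Of 232 tested miRNAs never at the floor 219 passed the F test, and of 103 at the floor on more arrays than not 97 passed, with median residual SDs of 0.268 and 0.150.

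The miRNAs named in the text followed a rule set before the data were examined, apart from those said to be chosen or named after their values were seen. It took miR-320a, miR-224, miR-132 and let-7g, which the study's title names, the 10 largest differences each way in the 2 pairs, the 3 largest each way for each line, the 20 largest SDs of line means, and up to 4 members of each list by range of line means or, in a list that passed, by p. The 31 lists were fixed at the same time, and every arm of a named hairpin counted. They were the let-7, miR-320, miR-200, miR-34, miR-29, miR-15/16, miR-30 and miR-181 families; the miR-224 and miR-452, miR-132 and miR-212, miR-17-92, miR-106b-25, miR-106a-363, miR-221/222, miR-183/96/182, miR-23/27/24 and miR-99/100/125 clusters; miR-31; the intestinal epithelial miR-192/194/215; the HOX-embedded miR-10/196; the stem cell clusters of miR-371, miR-372 and miR-373 and of miR-302 and miR-367; the 19q13 C19MC, 14q32 DLK1-DIO3, Xp11 miR-532 and Xq27 miR-514 clusters; a set of hypoxia and oncogenic miRNAs; and markers of fibroblast and smooth muscle, blood, endothelium, nerve and endocrine cells, and liver. The first set shares miR-17 and miR-18a with the miR-17-92 cluster.

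Between 258 and 441 human miRNAs were detected per array (median 365). The 75th percentile of the raw signal over the human probes detected on the same array ran from 281 to 678. It was not the divisor used for scaling, and was highest on the second WiDr and the first SW480 array, which detected the fewest. Of the viral miRNAs, 4.23% to 19.7% were called detected per array (median 14.1%). Spots of a probe varied by a median CV of 7.66%. The highest, 16.7%, was that of HT29 replicate 2, which also had the largest share of outlier spots, 7.79%, and was the 1 array that the scanner software marked for evaluation, while it marked the others as in range. The number of arrays limits the precision. In simulated data every line had the miRNA's mean over the 12 lines, with independent noise of its residual SD and the common floor. Real differences between lines and slides were thus left out, and 200 of the 466 miRNAs were shifted in 1 line. The F test then recovered 76% of the 2-fold and 89% of the 4-fold changes with 11 false calls among 266. The SW620 and SW480 contrast recovered 80% and 91% with 8 false calls, and the WiDr and HT29 contrast 89% and 90% with 6. For the single lines, 2-fold and 4-fold recovery and false calls were 93%, 97% and 2 in Caco2, 94%, 90% and 2 in HT29, 92%, 94% and 4 in LS1034, 97%, 94% and 9 in LS411N, 90%, 96% and 9 in LS513, and 93%, 97% and 2 in SW1116. They were 90%, 95% and 3 in SW1463, 94%, 96% and 4 in SW403, 90%, 92% and 5 in SW480, 93%, 93% and 6 in SW620, 94%, 96% and 5 in SW837, and 90%, 96% and 12 in WiDr.

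Alternatives were quantile normalization, the 75th percentile of all human probes, normexp with offset 50, the mean of all probes, the scanner's total gene signal, a floor at the first divided by 4, the deposited table, no filter or only the 199 miRNAs detected on all arrays, slide as a fixed or random block, the replicate number as a block, a variance trend with robust fit, only the 2 lines of a pair, a reference without the related line, adjustment over all 12 line comparisons, a 2-fold minimum, the distance as 1 minus r, and each array left out. The normexp correction had been planned on mean spot signals and was run on the median signals that the files hold. Run after the data had been seen were the fits without the 2 arrays of lowest detection, the first of SW480 and the second of WiDr, and with the viral signal regressed out. No genome coordinates are given, since the annotation used here is of another build than the array design. The survival of the lines after 5-FU and radiation, to which the study related the profiles, was not analysed here.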

Results

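Mature miRNAs were profiled in 12 established, untreated colorectal carcinoma lines: Caco2, HT29, LS1034, LS411N, LS513, SW1116, SW1463, SW403, SW480, SW620, SW837 and WiDr. The study related such profiles to how each line survived 5-FU, a fluoropyrimidine, and radiation, and its title names miR-320a, miR-224, miR-132 and let-7g. Each line had 3 arrays, except SW480 with 2, which made 35 arrays on 5 slides. Of 1205 human miRNAs on the array, 199 were detected on all arrays, 466 on every array of at least 1 line, and 646 on none. The first SW480 array and the second WiDr array detected the fewest, 293 and 258, and had the highest spread of negative controls, with SDs of 6.66 and 4.02 against a median of 1.67. Levels are log2 values relative to the 75th percentile of the array, with a floor at -7.01, given as mean ± SD over the arrays of a line, and differences are given with the standard error (SE) of the limma fit.

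The largest SDs of line means were those of miR-372 and miR-373. These and miR-371-3p, from a cluster active in embryonic stem cells, stood at 4.48 ± 0.21, 4.46 ± 0.23 and 2.66 ± 0.29 in Caco2 (n = 3) and at -0.85 ± 0.08, -1.08 ± 0.11 and -2.69 ± 0.05 in SW480 (n = 2), and lay at or near the floor in the other 10 lines. miR-215, miR-192 and miR-194, which are abundant in intestinal epithelium, were highest in SW1463 (4.26 ± 0.29, 4.88 ± 0.18 and 4.06 ± 0.09) and lowest in WiDr (-6.46 ± 0.15, -5.62 ± 0.42 and -5.56 ± 0.15), where they were measured on 1, 2 and 2 of 3 arrays, with ranges over the line means of 10.72, 10.51 and 9.62. miR-125b and miR-100, which share a primary transcript, were highest in WiDr at 3.56 ± 0.18 and 2.96 ± 0.18. miR-205, a miRNA of squamous epithelia, reached 2.81 ± 0.10 in HT29. miR-31, often raised in colorectal tumours, was highest in SW837 at 3.14 ± 0.30 and not well above background on any SW1463 array.

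The other miRNAs with the largest spread are given with the lines where they were high. Of these, miR-148a and miR-224 were found in most lines and were below background in 1 line alone. miR-499-5p, known from heart and slow muscle, was high in SW480 (2.37 ± 0.07) and LS1034 (0.10 ± 0.10). miR-142-3p, a blood cell miRNA, was highest in SW620 (2.37 ± 0.09), miR-150, a lymphocyte miRNA, in LS513 (0.37 ± 0.30), miR-483-3p, from an intron of IGF2, in LS1034 (0.31 ± 0.26), and miR-338-3p in SW1116 (0.71 ± 0.06). miR-424 was highest in SW480 (1.66 ± 0.01), miR-148a in SW403 (2.18 ± 0.28) and not above background in HT29, and miR-99b and miR-125a-5p, which share a cluster with let-7e, in HT29 (-0.11 ± 0.25 and -0.63 ± 0.13). miR-224 was highest in SW837 (1.93 ± 0.23) and not above background in SW480. Among these 20 miRNAs the adjusted p ran from 5.81e-37 for miR-372 to 1.08e-18 for miR-205.

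**Figure D1:**
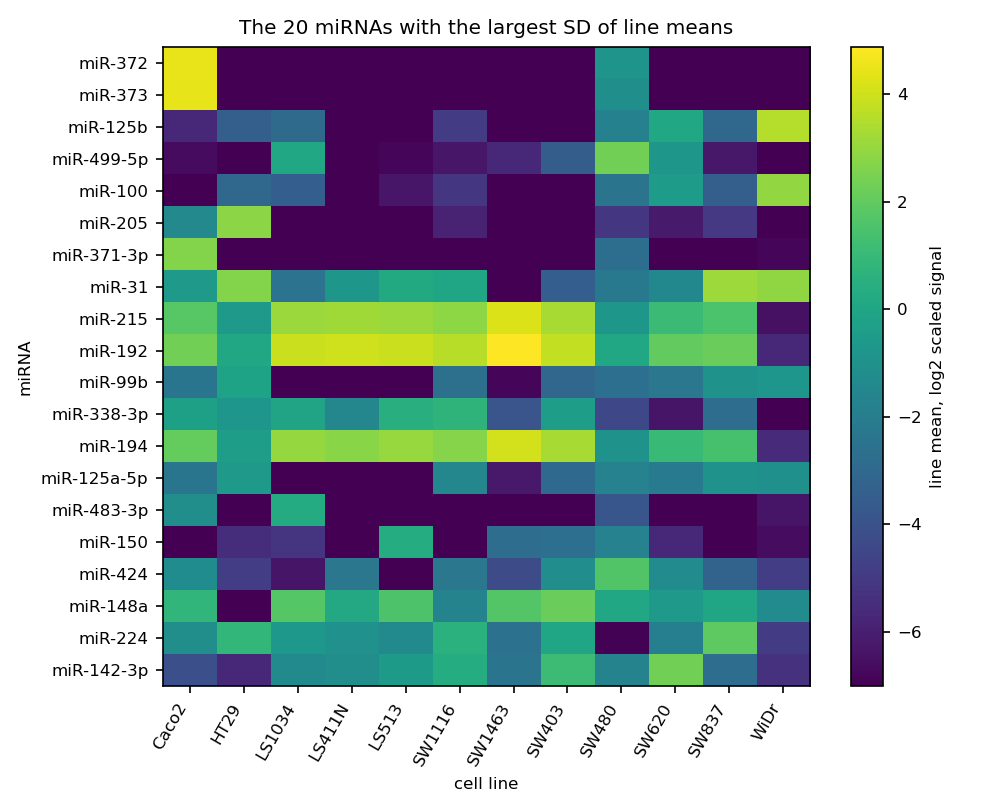
Heat map of the mean log2 level (relative to the 75th percentile of the array, colour scale) of the 20 miRNAs with the largest SD of line means, with miRNAs down and the 12 lines across. miR-372 and miR-373 reached 4.48 and 4.46 in Caco2, and miR-215 and miR-192 were lowest in WiDr.

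Of the 466 miRNAs tested, 438 (94.0%) differed between the lines by the moderated F test, 413 with a range of line means of at least 1 log2 and 90 of at least 4, values at the floor included. The median range was 2.27 log2 against a median residual SD of 0.243. The 6 viral miRNAs detected on all arrays ranged over 1.46 to 3.34 log2, so a range of this size was not particular to human miRNAs. With slide as a block 435 differed, and with slide as a random block 443. Restricted to the 199 miRNAs detected on all arrays, 189 differed. There were 25 miRNAs that were detected on all arrays of 1 line and on no array of any other line. Chosen after their values were seen, they included miR-302a, miR-302b, miR-302d, miR-367 and the liver miRNA miR-122 in Caco2, miR-145 in WiDr, miR-517a, miR-517b, miR-517c, miR-599 and miR-875-5p in SW480, and miR-508-3p, miR-509-3p and miR-514 in SW837.

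Nearly all lists changed in full by the F test, and each list's count adjusted over the list alone was equal. The test called 94.0% of all tested miRNAs, so a list changed in full says little about its members in particular. All tested members changed of let-7 (11), miR-320 (5), the miR-224 and miR-452 cluster (3), the miR-132 and miR-212 cluster (3), miR-17-92 (11), miR-106b-25 (6), miR-106a-363 (2), miR-200 (9), miR-192, miR-194 and miR-215 (5), miR-34 (4), miR-31 (2), miR-221 and miR-222 (4), miR-183, miR-96 and miR-182 (5), miR-23, miR-27 and miR-24 (10), miR-29 (6), miR-15 and miR-16 (8), miR-30 (11), miR-181 (7), the HOX-embedded miR-10 and miR-196 (8), the stem cell clusters (9), C19MC (4), Xp11 (14) and the hypoxia and oncogenic set (10). In the miR-99, miR-100 and miR-125 clusters 7 of 8 changed, in the 14q32 cluster 3 of 6 (miR-494 and miR-487b did not, with an adjusted p of 0.222 and 0.115), and in the Xq27 cluster 4 of 8 (miR-513a-5p did not, adjusted p = 0.213). Within miR-200, miR-141 and miR-200c ranged over 6.89 and 6.19 log2 with the lowest values in SW620. miR-34a, a p53 target, ranged over 5.87 log2 between LS513 (1.63 ± 0.25) and SW403 (-4.23 ± 0.27). miR-15a and miR-16 were lowest in LS1034, with ranges of 4.52 and 3.62, where miR-195 was not well above background, and miR-27a, miR-23a and miR-24 in SW1463, with ranges of 3.99, 3.54 and 3.38. miR-30a, with a range of 6.12, was highest in SW837, and miR-155 in SW1463, while it was not well above background in LS513, SW480, SW620 and WiDr.

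Markers of other cell types also differed between the lines, as did 94.0% of all tested miRNAs. All tested members changed of the lists for fibroblast and smooth muscle (4), blood (5), endothelium (2), nerve and endocrine cells (6) and liver (1). miR-145 was above background in WiDr alone, at -1.50 ± 0.08. The muscle miRNAs miR-1 and miR-133b stood at -1.75 and -2.03 in SW480 and at -2.32 and -2.15 in SW620. The endothelial miR-126 was highest in WiDr (-1.71), the red cell miRNA miR-451 in Caco2 (-2.77), the endocrine miR-375 in SW1463 (-0.06) and the neural miR-9 in WiDr (-1.81).

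The 4 miRNAs of the study's title all differed between the lines, and the study chose them on these lines, so their differences are not independent evidence. miR-224 ranged from 1.93 ± 0.23 in SW837 (n = 3) to SW480, where it was not well above background on either array (adjusted p = 4.35e-23). miR-132 ranged over 4.49 log2, from -2.41 ± 0.14 in LS411N to -6.90 ± 0.16 in SW403, measured there on 2 of 3 arrays (adjusted p = 3.23e-14). miR-320a ranged over 1.89 log2, from -0.21 ± 0.08 in WiDr to -2.10 ± 0.10 in SW1116 (adjusted p = 1.49e-11), and let-7g over 1.62 log2, from 2.61 ± 0.29 in LS411N to 0.99 ± 0.21 in Caco2 (adjusted p = 8.05e-07). Against the mean of the other 11, miR-320a was higher in 6 lines and lower in 5, miR-224 higher in 6 and lower in 4, miR-132 higher in 4 and lower in 4, and let-7g higher in 2 and lower in 2. Adjusted over the list alone, these counts were 6 and 5, 7 and 4, 5 and 4, and 3 and 2. Their probes correlated over the arrays at 0.969 or more.

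SW480, the line in which the study transfected miRNA mimics, had miR-224 at least 39.4-fold lower than the mean of the other 11 (adjusted p = 4.47e-22). miR-320a was higher there by 0.39 log2 (SE 0.131, adjusted p = 0.0165), a call that was lost without SW480 replicate 1 (0.34, adjusted p = 0.171), without SW480 replicate 2 (0.44, adjusted p = 0.0643), with the percentile of all probes (0.23, adjusted p = 0.265) and with normexp (0.35, adjusted p = 0.0656). miR-132 and let-7g differed by -0.01 (adjusted p = 0.974) and -0.04 (adjusted p = 0.878). With slide as a block miR-224 was lower there too (adjusted p = 4.39e-20), and the other differences were 0.42 for miR-320a, 0.0056 for miR-132 and -0.05 for let-7g.

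**Figure D2:**
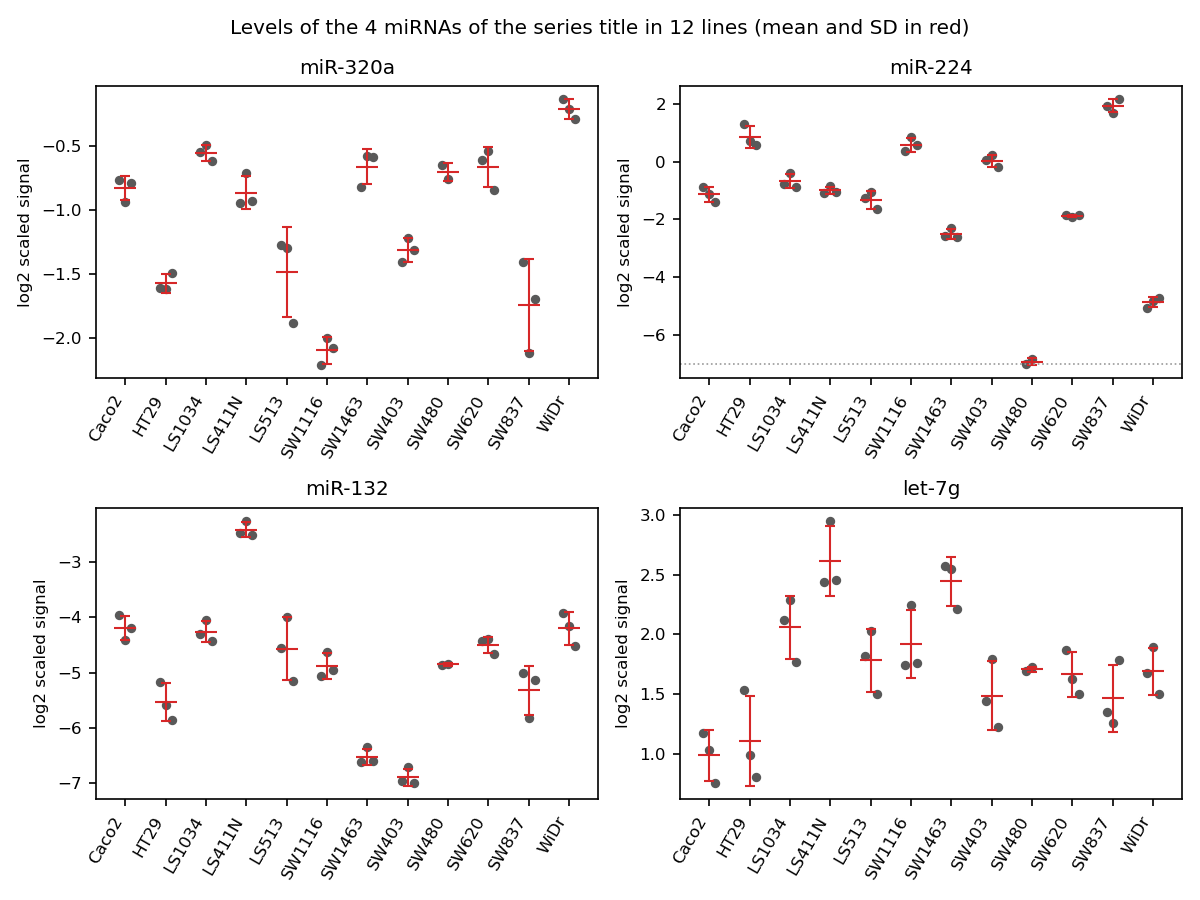
Log2 level (relative to the 75th percentile of the array) of miR-320a, miR-224, miR-132 and let-7g in the 12 lines, where each point is 1 array, the red marks are the mean and SD, and the dotted line in the miR-224 panel is the floor. The miR-224 values of both SW480 arrays lie at or near the floor, and the WiDr arrays stand at -4.87.

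SW480 and SW620 are related lines, from a primary tumour and a lymph node metastasis, and the comparison shows how they differ. SW620 had far less of the epithelial miRNAs miR-141 and miR-200c, by -4.82 log2 (SE 0.222, 28.3-fold) and -4.65 log2 (SE 0.174, 25.2-fold; SW620 n = 3, SW480 n = 2, adjusted p = 1.85e-16 and 1.54e-18). Of the stem cell cluster, miR-372, miR-373 and miR-371-3p, which SW480 expressed, were below background in SW620, at least 59.6-fold, 50.9-fold and 16.7-fold lower. miR-875-5p and miR-599, which lie next to each other in the genome, were at least 85.6-fold and 25.7-fold lower. SW620 had more of the blood cell miRNAs miR-142-3p (4.09 log2, SE 0.324, 17.0-fold) and miR-142-5p (4.66, SE 0.342, measured on 1 of 2 SW480 arrays), of miR-224 (at least 20.1-fold), of miR-135a (at least 17.2-fold) and of miR-375 (2.78 log2, SE 0.263).

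Among the lists, the stem cell clusters fell: 4 of 9 members were lower in SW620 and 0 higher (camera, adjusted p = 0.00999, mean difference -2.17). The median of the list was 0, also with dim members at their bounds, since the other 5 were at the floor in both lines. All 11 members of miR-17-92, a cluster that drives proliferation, were higher, with a median of 1.22 log2, among them miR-19b-1* (2.21, SE 0.310), miR-92a (1.18) and miR-18a (0.73). The list as a whole did not pass (adjusted p = 0.354 with an estimated correlation). All 5 members of miR-192, miR-194 and miR-215 were higher (median 1.87, adjusted p = 0.463 with an estimated correlation), all 3 of the miR-224 and miR-452 cluster (adjusted p = 0.204), and 5 of 9 of miR-200 were lower (median -0.54, mean -1.79, adjusted p = 0.354; adjusted over the list alone, 6). Of C19MC, with 4 members tested of 45 on the array, 3 were lower, with miR-517a at least 3.37-fold (0 of 4 with normexp). These were miR-517a, miR-517b and miR-517c, tested only because SW480 alone had them, so their direction was fixed in advance. Of miR-183, miR-96 and miR-182 4 of 5 were lower, with miR-96 at -1.08. None of these directions turned under any scaling. Median, mean and test differed in sign for the miR-10 and miR-196 list (0.40, -0.11 and down; 4 higher, 3 lower) and for miR-106b-25 (0.03, 0.14 and down; 0 changed). With the preset correlation 6 lists passed.

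The markers of other cell types moved both ways alongside. miR-150 and miR-126 were lower in SW620 by -3.88 (SE 0.248) and -1.77, miR-142-3p was higher, 2 of 5 blood members rose and 2 fell, and the muscle miRNAs miR-1 and miR-133a were lower by -0.57 and -0.55. Of the nerve and endocrine list 5 of 6 were higher. Other large differences were miR-592 and miR-342-3p, at least 14.3-fold and 14.01-fold lower, miR-371-5p, lower by -3.11 (SE 0.374), and miR-582-3p, miR-582-5p, miR-92a-1* and miR-4313, higher by at least 4.13-fold, 2.17, 2.37 and 2.29 log2. miR-92a-1* and miR-4313 were measured on 1 of 2 SW480 arrays, and the call of miR-4313 was lost without the 2 arrays of lowest detection. Of the study's miRNAs, miR-320a differed by 0.04 (adjusted p = 0.990), miR-132 by 0.35 (adjusted p = 0.338) and let-7g by -0.04 (adjusted p = 1).

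In all, 158 of 466 miRNAs changed between SW620 and SW480, 94 higher and 64 lower, 93 of them at least 2-fold. Of the 158, 20 were below background in SW620 and 18 in SW480. With slide as a block the count was 165, and on the slide that held both lines 158 of 158 differences had the same direction (1 array each), as had all 21 named. These arrays also entered the fit that made the calls, so the agreement in direction is no independent check. The count was 104 with normexp and 61 among the miRNAs detected on all arrays. The stem cell list passed with slide as a block (adjusted p = 0.0212) but not with the percentile of all probes (adjusted p = 0.568), normexp (0.523), the total gene signal (0.0918) or the viral signal regressed out (0.463), nor without Caco2 replicate 1 (0.0578), and 0 lists passed in these settings and among the miRNAs detected on all arrays. The number was 2 with the lower floor and without SW480 replicate 1, SW480 replicate 2 or the 2 arrays of lowest detection.

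WiDr is held to be a derivative of HT29, and the comparison shows how far apart the 2 stocks were. WiDr had almost none of the intestinal miRNAs that HT29 carried: miR-215, miR-192 and miR-194 were lower by -5.87 (SE 0.251), -5.72 (SE 0.308) and -5.17 log2 (SE 0.204), or 58.4-fold, 52.8-fold and 36.0-fold (n = 3 each; measured on 1, 2 and 2 of the 3 WiDr arrays). miR-205 was at least 526-fold lower and miR-338-3p at least 43.7-fold lower. WiDr had more miR-125b (6.99 log2, SE 0.244, 127-fold), miR-100 (63.9-fold) and miR-99a (5.84, SE 0.261, 57.3-fold), and miR-130a, miR-148a and the smooth muscle miRNA miR-145 were at least 100.1-fold, 51.2-fold and 43.2-fold higher. The neural miR-9 and miR-9* were at least 34.9-fold and 26.6-fold higher.

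The miR-224 and miR-452 cluster fell in WiDr: miR-224 by -5.74 (SE 0.184, 53.3-fold), miR-452 at least 15.2-fold and miR-224* at least 4.52-fold (3 of 3 lower, camera adjusted p = 0.0414, median -4.70, and -3.92 with dim members at their bounds). This was the 1 list of 30 that passed, and its adjusted p was 0.0920 with slide as a block, with medians of -4.66 and -4.43 on the 2 slides that held both lines. All 5 members of miR-192, miR-194 and miR-215 were lower (adjusted p = 0.209 with an estimated correlation), as were 5 of 9 of miR-200 (median -1.88, adjusted p = 0.448 with an estimated correlation). All 5 of miR-183, miR-96 and miR-182 were higher (median 1.43, adjusted p = 0.333), with miR-96 at 1.59 and miR-182 at 1.41, and all 5 of miR-320 (median 1.11, adjusted p = 0.636). These directions did not turn under any scaling. The miR-99, miR-100 and miR-125 list had 4 members higher and 3 lower, the miR-10 and miR-196 list 2 and 5, and the Xp11 list 9 and 0. With the preset correlation 4 lists passed. The test was down but median and mean above 0 for the miR-181 family (0.10 and 0.15) and the miR-221 and miR-222 cluster (0.25 and 0.23), and median and mean parted for the miR-15 and miR-16 family (-0.06 and 0.03, test down). With a median of 0 and a mean above 0, the test was also down for the stem cell (0.19), blood (0.245) and Xq27 (0.042) lists.

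Beside the fall of the intestinal miRNAs, the endothelial markers were higher in WiDr, miR-126 by 3.97 log2 and miR-126*, whose probes correlated poorly, at least 4.47-fold (2 of 2, adjusted p = 0.209). miR-145 was higher. Of the 5 blood members miR-150 was at least 1.70-fold lower, not well above background on any WiDr array, and miR-150* of the same hairpin, named after its value was seen, was higher by 2.06 (SE 0.359). miR-1, miR-133a, miR-133b and miR-451 were below background in both lines. miR-4324 and miR-342-3p were at least 40.4-fold and 28.3-fold higher, miR-582-5p was at least 6.80-fold lower and miR-10a* was lower by -2.94. Of the study's miRNAs, miR-320a was higher in WiDr by 1.37 (SE 0.146, adjusted p = 7.59e-09) and miR-132 by 1.34 (SE 0.229, adjusted p = 1.81e-05). let-7g was higher by 0.58 (SE 0.207, adjusted p = 0.0217), which turned to -0.01 with the percentile of all probes and was lost without HT29 replicate 2 (0.52), HT29 replicate 3 (0.43) or WiDr replicate 2 (0.48).

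Between WiDr and HT29, 219 of 466 miRNAs changed, 138 higher and 81 lower in WiDr, 121 of them at least 2-fold, with 21 below background in WiDr and 25 in HT29. The balance of directions depended on the scaling: it was 109 and 109 with quantile normalization, 67 and 148 with the percentile of all probes, 137 and 43 with normexp and 93 and 118 with the deposited table. The median difference of all miRNAs, 0.10, moved by -0.21, 0.26 and -0.14 in the last 3 of these. With slide as a block 226 changed, and 208 without HT29 replicate 2, the 1 array that the scanner software marked for evaluation. On the slides that held both lines, 217 (99.1%) and 214 (97.7%) of the 219 had the same direction, as had all 23 named. The calls came from a fit with these same arrays, so this agreement is not independent. The call of the miR-224 and miR-452 cluster was lost, with 0 lists passing, with quantile normalization (adjusted p = 0.135), the percentile of all probes (0.202), the mean of all probes (0.0803), the total gene signal (0.105) or the deposited table (0.0750), without the 2 arrays of lowest detection (0.0531), among the miRNAs detected on all arrays, and without any 1 of HT29 replicate 1, HT29 replicate 2, LS513 replicate 3, SW1463 replicate 1, SW837 replicate 2 or WiDr replicate 1.

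**Figure D3:**
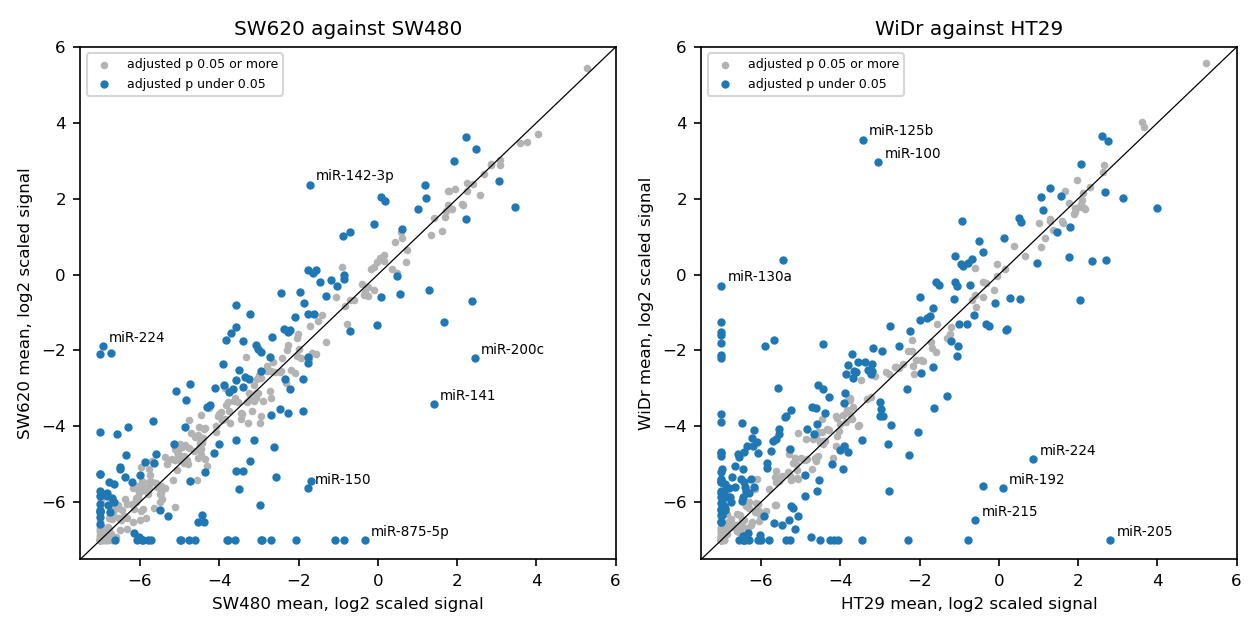
Mean log2 level of each of the 466 miRNAs in SW480 (x axis) and SW620 (y axis), and in HT29 (x axis) and WiDr (y axis), relative to the 75th percentile of the array. Blue points have an adjusted p under 0.05 and grey points do not, the diagonal marks equal levels, and miR-141 and miR-200c lie below it in the first panel and miR-125b above it in the second.

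Each line was compared with the mean of the other 11, and the miRNAs of largest difference are said to mark it. A miRNA that marked a line need not be highest there. For example, miR-9 and miR-125b were highest in WiDr, miR-31 in SW837, miR-142-3p in SW620 and miR-499-5p in SW480. Caco2, a line that differentiates to enterocyte-like cells, was set apart by the stem cell clusters: miR-372 was at least 1737-fold, miR-373 at least 1735-fold, miR-371-3p at least 547-fold and miR-302b at least 4.74-fold higher. It had little miR-10a (-6.18 log2, SE 0.140, 72.3-fold lower), let-7b (-4.10, SE 0.185, 17.2-fold) and miR-135b (-4.08, SE 0.125, 16.9-fold). Of 15 members of the stem cell clusters on the array 9 were tested. Of these, miR-302a, miR-302b, miR-302d and miR-367 were tested only because Caco2 alone had them, which fixed their direction in advance. The median and p of the list thus rest in part on the filter. All 9 were higher (median 3.23, or 3.02 with dim members at their bounds, camera adjusted p = 0.000276), the 1 test of 360 that passed. It passed with slide as a block (adjusted p = 0.00201), and the medians on the 3 slides with Caco2 were 3.09 or more, but not with normexp (adjusted p = 0.364) or the viral signal regressed out (adjusted p = 0.195). The number of passing tests was 0 among the miRNAs detected on all arrays, 19 with quantile normalization, 18 with the deposited table, 9 with normexp, 3 without Caco2 replicate 3, 17 without SW620 replicate 3 and 109 with the preset correlation.

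Other groups moved in Caco2 in most members without passing as lists. All 14 members of the Xp11 cluster were higher, with a median of 2.33 log2 and miR-660 and miR-362-3p at 2.36 and 2.49 (adjusted p = 0.150 with an estimated correlation). Of let-7, a family that restrains growth and rises with differentiation, 10 of 11 were lower, with a median of -1.74, let-7c at -3.46 and let-7e higher by 0.64, though not called with the percentile of all probes (adjusted p = 0.181). Of the miR-10 and miR-196 list 7 of 8 were lower (adjusted over the list alone, 8; median -2.14, miR-10b at -3.78, miR-196b at -2.25, adjusted p = 0.0797), of miR-29 5 of 6 (miR-29a at -2.94, adjusted p = 0.0988), and of miR-221 and miR-222 4 of 4 (miR-222 at -1.71, adjusted p = 0.216). These directions did not turn under any scaling. Of the markers of other cell types, miR-122 was above background in Caco2 alone, at -3.14, miR-451 was highest there, and 2 of 4 fibroblast and smooth muscle members were higher and 2 lower. Of the blood list 1 of 5 was higher, miR-451, and 3 were lower, with miR-142-3p at -2.57 (adjusted p = 0.462 for the list), and of the nerve and endocrine list 3 of 6 were higher and 3 lower, with miR-375 at -2.41 (adjusted p = 0.805). The medians of both lists lay below 0 on all 3 slides with Caco2. The test was down but median and mean above 0 for the miR-224 and miR-452 (0.30 and 0.17), miR-106b-25 (0.06 and 0.07), miR-192, miR-194 and miR-215 (0.29 and 0.19), miR-23, miR-27 and miR-24 (0.17 and 0.05) and Xq27 (0.09 and 0.24) lists, and up with a mean below 0 for the hypoxia and oncogenic set (0.31 and -0.00055). In Caco2 283 miRNAs changed, 101 of them lower and 64.3% higher, and 126 at least 2-fold. The directions were 142 higher (53.2%) with quantile normalization, 95 and 137 with the percentile of all probes, 149 and 51 with normexp and 114 and 135 with the deposited table, and the median of all miRNAs, 0.24, moved by -0.26, -0.37, -0.0049 and -0.28 in turn.

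HT29 was marked by miR-205 (at least 398-fold higher), miR-99b (at least 13.3-fold) and miR-31 (at least 12.99-fold), and lacked miR-148a (at least 165-fold lower). The level of miR-31 was higher still in SW837. miR-142-3p was lower by -4.23 log2 (SE 0.214, 18.8-fold), and miR-95 was not well above background. In HT29 308 miRNAs changed, 100 higher and 208 lower, 113 at least 2-fold, against 135 and 158 with quantile normalization, 126 and 139 with the percentile of all probes and 138 and 141 with the deposited table, which moved the median of -0.29 by 0.18, 0.19 and 0.25, and 293 changed without HT29 replicate 2. WiDr differed from the other 11 mainly in miR-215 (-8.55, SE 0.186, 374-fold lower), miR-192 (-8.43, 346-fold) and miR-194 (-7.58, 192-fold), measured on 1, 2 and 2 of the 3 WiDr arrays, and in miR-125b, miR-100 and miR-130a, which were at least 260.3-fold, 204-fold and 84.8-fold higher. In WiDr 276 miRNAs changed, 127 higher and 149 lower, 117 at least 2-fold, against 82 and 199 with the percentile of all probes and 166 and 70 with normexp, which moved the median of -0.10 by -0.14 and 0.34.

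Among the 3 LS lines, LS1034 was marked by miR-483-3p (at least 80.7-fold higher), miR-499-5p (at least 31.2-fold) and miR-193a-3p (3.55 log2, SE 0.140, 11.7-fold), LS411N by miR-193a-3p (3.09, SE 0.140, 8.54-fold), miR-549 (at least 6.73-fold) and miR-132* (at least 6.62-fold), and LS513 by miR-150 (at least 47.5-fold), miR-338-3p (at least 7.03-fold) and miR-34a (2.59, SE 0.156, 6.03-fold). The lowest were miR-125a-5p in all 3, not well above background on any of their arrays, with miR-99b in LS1034 and LS411N, miR-424 in LS1034, miR-125b in LS411N, and miR-193b and miR-424 in LS513, where they were at least 20.5-fold and 19.1-fold lower. In LS1034 285 miRNAs changed, 129 higher and 156 lower, 89 at least 2-fold; in LS411N 263, 134 higher and 129 lower, 84 at least 2-fold; and in LS513 244, 82 higher and 162 lower, 78 at least 2-fold. In LS513 the directions were 129 and 128 with quantile normalization, 154 and 113 with the percentile of all probes and 117 and 134 with the deposited table, which moved the median of -0.09 by 0.10, 0.24 and 0.09.

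SW1463 was marked by miR-155 (at least 21.8-fold higher), miR-375 (11.3-fold) and miR-215 (3.15, SE 0.186, 8.85-fold), and lacked miR-31 and miR-31* (at least 93.6-fold and 27.9-fold lower), while miR-99b was measured on 2 of 3 arrays. SW403 was marked by miR-455-3p (at least 21.4-fold), miR-552 (at least 19.3-fold) and miR-142-3p (3.16, SE 0.214, 8.94-fold), with miR-34a lower by -3.81 (SE 0.156), miR-34b* at least 11.3-fold lower and miR-125b not well above background. SW837 was marked by miR-30a (4.84, SE 0.139, 28.7-fold), miR-30a* (at least 20.6-fold) and miR-31 (at least 18.6-fold), with miR-19b-1* at -2.83 (7.13-fold lower), miR-375 at -2.73 (6.64-fold lower) and miR-181a* not well above background. SW1116 was marked by miR-338-3p, miR-9 and miR-9* (at least 8.49-fold, 7.94-fold and 7.33-fold higher), with miR-193a-3p at -2.85 (measured on 1 of 3 arrays) and miR-455-3p and miR-150 not well above background. The level of miR-9 was higher still in WiDr.

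In SW1463 328 miRNAs changed, 189 higher and 139 lower, 143 at least 2-fold, and in SW403 291, 153 higher and 138 lower, 112 at least 2-fold. With the viral signal regressed out after the data had been seen, 160 changed in SW1463 and 178 in SW403, the 2 lines with the highest viral signal. In SW1116 242 changed, 90 higher and 152 lower, 81 at least 2-fold, against 113 and 106 with the percentile of all probes, which moved the median of -0.18 by 0.13. In SW837 304 changed, 96 higher and 208 lower, 102 at least 2-fold, against 124 and 158 with quantile normalization, 123 and 148 with the percentile of all probes, 66 and 315 with normexp and 140 lower (47.2% higher) with the total gene signal. The median of all miRNAs in SW837, -0.25, moved by 0.16, 0.16, -0.33 and 0.06 in turn.

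Against the other 11, SW480 was marked by miR-499-5p (at least 173-fold higher), miR-875-5p (at least 89.8-fold) and miR-424 (at least 36.3-fold), and besides miR-224 its lowest miRNAs were miR-155 and miR-452, which were not well above background. SW620 was marked by miR-135a (at least 25.7-fold), miR-142-3p (4.51 log2, SE 0.214, 22.8-fold) and miR-125b (at least 19.2-fold), and by low miR-141 (-5.49, SE 0.147, 45.0-fold), miR-200c (-5.16, SE 0.115, 35.7-fold) and the epithelial differentiation miRNA miR-203 (-4.75, SE 0.172, 26.9-fold). The level of miR-125b was higher still in WiDr. In SW480 211 miRNAs changed, 99 higher and 112 lower, 90 at least 2-fold, against 96 and 174 with quantile normalization and 77 and 149 with the percentile of all probes. In SW620 275 changed, 139 higher and 136 lower, 97 at least 2-fold.

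With slide as a block the counts for the single lines were 291 in Caco2, 311 in HT29, 295 in LS1034, 265 in LS411N, 260 in LS513, 241 in SW1116, 324 in SW1463, 294 in SW403, 284 in SW620, 316 in SW837 and 282 in WiDr, and in SW480 47.6% of the 466 tested. Within slides 2 to 5, between 89.8% and 99.3% of each line's changed miRNAs had the same direction against the other arrays of the slide. Such shares are not independent of the calls, which used the same arrays. Normexp moved several counts by over 1.5 times, to 193 in HT29, 181 in LS1034, 160 in LS411N, 157 in LS513, 151 in SW1116, 174 in SW403, 114 in SW480 and 170 in SW620, and to 46.1% of the 466 tested in SW1463. Further shifts above 0.1 of the median over the same 466 miRNAs were 0.11, 0.16, 0.18, 0.11 and 0.34 with normexp in SW620 against SW480, HT29, LS411N, SW620 and WiDr, and 0.12, 0.12, -0.12, 0.25 and -0.15 with the total gene signal in Caco2, LS513, SW1116, SW403 and WiDr. The shift was -0.14 in SW1463 with quantile normalization, and 0.15, -0.13 and 0.18 in SW1116, SW1463 and SW837 with the deposited table. With the lower floor it was -0.11 in HT29, 0.10 in SW1463 and 0.11 in SW403, and with the viral signal regressed out -0.16 in Caco2, 0.16 in HT29, -0.12 in SW1463, 0.17 in SW480 and 0.14 in SW620. On slide 1, where 3 arrays of other lines were the reference, the shares were 76.4% in LS411N, 80.2% in SW1116, 85.4% in SW1463 and 79.7% in SW403.

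The last comparison asked whether lines of 1 origin were closer to each other than other lines. SW480 and SW620 were each other's nearest line, at a root mean square difference of 1.22 log2, and HT29 was the line nearest to WiDr, at 1.49, while SW837 was nearer to HT29, at 1.15. The mean of the 2 related pairs, 1.35, lay below the median of 1.52 over all 66 pairs, but the exact one-sided test over 1485 choices of 2 pairs gave p = 0.228. With only the miRNAs detected on all arrays the mean was 0.963 (exact p = 0.0498), and with slide as a block it was 1.36. The closest pair was SW1463 and SW403 at 0.916, followed by LS411N and LS513 at 0.978 and SW1116 and SW837 at 0.981. Caco2 stood farthest from the rest, with a median of 1.85 and LS411N as its nearest line at 1.68. Arrays of the same line differed by a median of 0.395, and correlated at 0.977 to 0.997, against 0.757 to 0.954 for arrays of different lines.

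**Figure D4:**
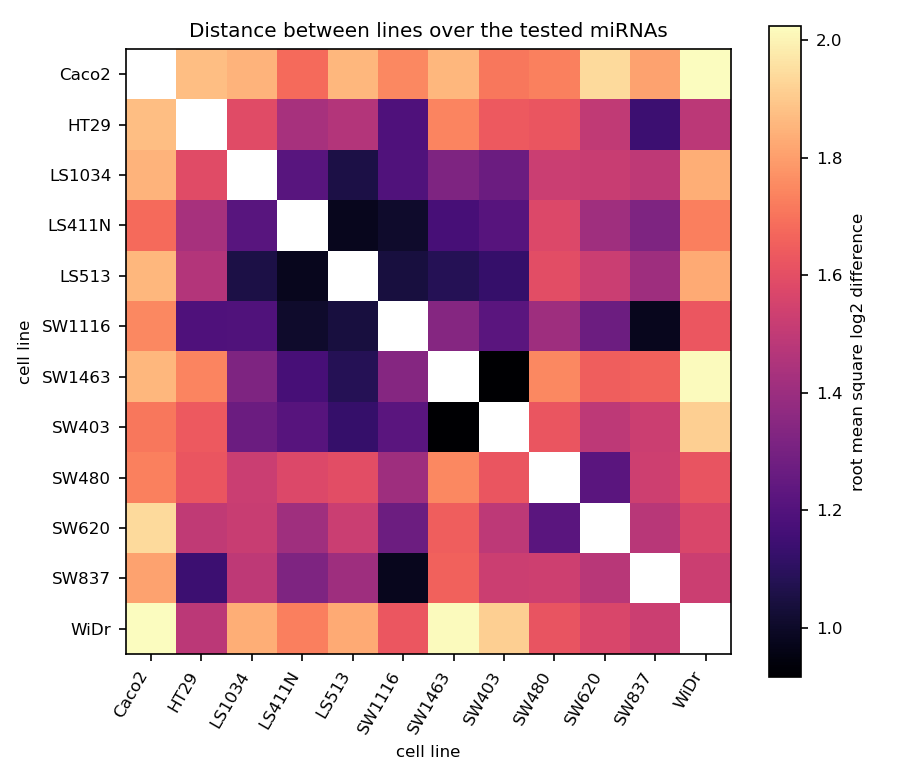
Root mean square log2 difference of line means over the 466 miRNAs for each pair of the 12 lines, on a colour scale. SW1463 and SW403 form the closest pair at 0.916, SW480 and SW620 lie at 1.22, and HT29 and WiDr at 1.49.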

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

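The tests weighed for WiDr, the slide column and the virus were chosen only after the result was seen, though they use the planned fit without 1 array and the planned distances, and so was the fit with the viral signal regressed out.

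Probes for viral miRNAs, which no comparison used, gave a signal above background on all 35 arrays for 6 of 142 viral miRNAs. The mean log2 levels were -2.73 for kshv-miR-K12-3, -3.43 for ebv-miR-BART19-3p, -3.56 for ebv-miR-BART13, -3.74 for hsv2-miR-H25, -3.93 for hsv1-miR-H18 and -4.41 for hsv2-miR-H10, where the median tested human miRNA stood at -4.78. Their ranges over the lines ran from 1.46 for hsv2-miR-H25 to 3.34 for ebv-miR-BART19-3p, against a median of 2.27 for the tested human miRNAs. An infection would raise many miRNAs of 1 virus, but the highest share of a virus detected on all arrays was 9.09%, for hsv2, and 110 of the 142 were never detected. Nonspecific hybridisation of human RNA to these probes may account for the signal, which was not tested and stays open. Apart from an infection, no biological explanation was tested.

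WiDr and HT29 differed in 219 miRNAs although HT29 was the line nearest to WiDr. Low signal of the second WiDr array is argued against by a count of 211 without it. RNA of fibroblast, blood or endothelial cells in place of epithelial RNA was taken to lower all epithelial miRNAs alike, an untested premise. The miR-200 family fell too, by a median of -1.88. Its median lay 3.29 log2 above that of miR-192, miR-194 and miR-215, beyond the SD of 1.22 of its members. Under that premise such RNA is argued against as the whole cause. Of 11 markers of those cells 4 were higher, led by miR-145 at -1.50 and miR-126 at -1.71, and 1 was lower. The markers miR-1, miR-133a, miR-133b, miR-142-5p and miR-451 were at the floor in both lines. The markers that rose go with the explanation, so a share of such RNA stays open. Another line under the WiDr label cannot be told apart from cultures that drifted, since a distance of 1.49 fits both. A difference between the stocks themselves also stays open, as untested.

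Which lines resembled each other was weighed against the slide layout and the signal on viral probes, taken as a stand-in for nonspecific signal. Lines of the same slide column lay at a mean distance of 1.4616 against 1.5025 for others (exact one-sided p = 0.229 over 15400 partitions), and at 1.4831 over the 10 same-column pairs that are not related lines. Position in the column stays open, since both related pairs share a column and this p lay between the threshold of 0.05 and the 0.5 set to exclude it. With the viral signal regressed out SW1463 and SW403 kept rank 1 of 66 pairs, at 0.897 after 0.916. Their mean viral signals were the highest and nearly alike, -2.76 and -3.01, so the regression could hardly change their own distance. The rank could move only through the other pairs, and the median distance of all pairs was 1.30 after 1.52. Such signal shared by the 2 lines therefore stays open as a cause of their closeness. The same regression changed the nearest line of 6 of 12 lines, and SW480 and SW620 were no longer each other's nearest.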

How the results depend on the processing

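The tests without the 2 arrays of lowest detection and with the viral signal regressed out were chosen only after the result was seen. Of 167 called or studied results of named miRNAs, 134 kept direction and side of the threshold in every other setting that tested them, the sets without 1 array aside, and 146 in every set without 1 array. Signal over background limits these arrays, since values at the floor have no order. Without any 1 array the F test called 432 to 445 miRNAs and SW620 against SW480 127 to 167, the fewest without SW480 replicate 1, and every count stayed within 1.5 times its value. Where SW480 was left with 1 array, that array is assumed to vary like the other lines. The slide as a random block gives no list value, and miR-224 and miR-132 have no value among miRNAs detected on all arrays. Counts are followed by their percent of the miRNAs tested, and lists are given for SW620 against SW480, WiDr against HT29 and the single lines. The cause was not tested for any value below, except where fewer miRNAs were tested or the call was stricter.

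With quantile normalization 0 lists passed for WiDr against HT29 and 19 for the lines, and the log2 differences were 0.13 for miR-132 in SW1116 and 0.26 for let-7g in WiDr. With the percentile over all human probes 0, 0 and 2 lists passed, miR-320a was 0.23 in SW480 and -0.17 in Caco2, miR-224 -0.13 in Caco2, miR-132 0.17 in SW1116, and let-7g -0.012 between WiDr and HT29 and 0.0011 in SW837. With normexp 104 (22.3%) changed between SW620 and SW480, and 193 (41.4%) in HT29, 181 (38.8%) in LS1034, 160 (34.3%) in LS411N, 157 (33.7%) in LS513, 151 (32.4%) in SW1116, 46.1% in SW1463, 174 (37.3%) in SW403, 114 (24.5%) in SW480 and 170 (36.5%) in SW620. With it 0 lists passed for SW620 against SW480 and 9 for the lines, miR-320a was 0.35 in SW480, miR-224 -0.030 in Caco2 and -0.25 in LS513, and miR-132 -0.011 in LS513. With the mean of all probes 0 lists passed for WiDr against HT29, let-7g was 0.030 in SW480 and miR-320a -0.0090 between SW620 and SW480. With the total gene signal 0 and 0 lists passed for the pairs, miR-132 and let-7g were 0.081 and 0.089 in SW480, miR-320a -0.11 between SW620 and SW480, and let-7g -0.0081 in SW1116. With the lower floor 2 lists passed for SW620 against SW480 and 6 for the lines. With the deposited values 0 lists passed for WiDr against HT29 and 18 for the lines, let-7g was 0.094 in SW480 and 0.10 in SW403, miR-320a -0.23 between SW620 and SW480, and miR-224 -0.10 in Caco2 and -0.078 in LS513.

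With no filter 3, 5 and 95 lists passed. Among the 199 miRNAs detected on all arrays, a smaller set by construction, 189 (94.97%) differed by the F test, 61 (30.7%) between SW620 and SW480 and 103 (51.8%) between WiDr and HT29, and 121 (60.8%) in Caco2, 137 (68.8%) in HT29, 114 (57.3%) in LS1034, 120 (60.3%) in LS411N, 104 (52.3%) in LS513, 108 (54.3%) in SW1116, 142 (71.4%) in SW1463, 113 (56.8%) in SW403, 65 (32.7%) in SW480, 119 (59.8%) in SW620, 132 (66.3%) in SW837 and 112 (56.3%) in WiDr. The distance of the related pairs was then 0.963 (exact one-sided p = 0.0498), and 0, 0 and 0 lists passed. At least 2-fold, a stricter call, were 93 (19.96%) between SW620 and SW480, 121 (26.0%) between WiDr and HT29, and 126 (27.04%) in Caco2, 113 (24.2%) in HT29, 89 (19.1%) in LS1034, 84 (18.0%) in LS411N, 78 (16.7%) in LS513, 81 (17.4%) in SW1116, 143 (30.7%) in SW1463, 112 (24.03%) in SW403, 90 (19.3%) in SW480, 97 (20.8%) in SW620, 102 (21.9%) in SW837 and 117 (25.1%) in WiDr. With the preset correlation 6, 4 and 109 lists passed. With slide as a block 0 lists passed for WiDr against HT29, miR-132 was 0.0056 in SW480, miR-320a -0.039 between SW620 and SW480 and let-7g -0.031 in LS513. Against a reference without the related line miR-132 was 0.026 in SW480. Without the 2 arrays of lowest detection 2, 0 and 4 lists passed, and miR-320a and miR-132 were 0.34 and 0.0088 in SW480. With the viral signal regressed out 160 (34.3%) changed in SW1463 and 178 (38.2%) in SW403, 0 lists passed for SW620 against SW480 and 2 for the lines, and miR-132 was -0.055 in SW620.

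Leaving out 1 array at a time, 0 to 2, 0 to 1 and 1 to 17 lists passed. The lowest and highest differences were 0.34 and 0.44 for miR-320a and -0.035 and 0.018 for miR-132 in SW480, -0.022 and 0.13 for miR-320a and -0.15 and 0.040 for let-7g between SW620 and SW480, -0.040 and 0.26 for miR-224 and -0.079 and 0.18 for let-7g in LS513, -0.17 and 0.055 for miR-132 in SW1116, and -0.16 and 0.036 for let-7g in WiDr. The call of miR-320a in SW480 was lost without SW480 replicate 1 (0.34) and without SW480 replicate 2 (0.44). For SW620 against SW480 0 lists passed without Caco2 replicate 1, and 2 without SW480 replicate 1 or 2. For WiDr against HT29 0 passed without HT29 replicate 1 or 2, LS513 replicate 3, SW1463 replicate 1, SW837 replicate 2 or WiDr replicate 1. For the lines 3 passed without Caco2 replicate 3 and 17 without SW620 replicate 3.

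The replicate numbers were not taken to pair the arrays, since 83 of 187 same-numbered pairs, and not every one, had a residual correlation over 0.1. The median residual correlation was 0.073 for arrays of the same number and -0.035 for arrays of different numbers, against 0.15 and -0.051 for the same and different slides, and 19 of 35 arrays correlated best with one of their own number. Replicate number went with the slide: number 1 lay on slides 4 and 5, number 2 on slides 3 and 4, and number 3 on slides 1 and 2. Likeness of same-numbered arrays thus cannot be told apart from that of shared slides. With the replicate number as a block 440 miRNAs differed by the F test, 169 between SW620 and SW480 and 225 between WiDr and HT29, and let-7g was 0.045 between SW620 and SW480.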

Other observations

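The restriction to pairs detected in at least 6 lines was chosen only after the result was seen, while the test of neighbouring genes and the other splits were fixed before theirs, with some examples of such pairs already known.

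miRNAs whose genes lie next to each other varied together over the lines. In a RefSeq gene table of assembly GRCh38.p14, used only for which genes neighbour each other, 389 of 466 miRNAs were found by name. Over 220 pairs within 10000 bp the median correlation of the 12 line means was 0.857, across genes, which are not independent replicates, against 0.02 over all pairs, and 138 pairs were over 0.8. The pairs came from 131 miRNAs, and the Xp11 cluster, with 14 tested members, supplied more of them than any other. This cluster therefore weighs heavily in the median and among the pairs over 0.8. After shuffling the positions 10000 times the highest median was 0.219 (permutation p = 1e-04, the smallest these permutations can give). The median was 0.892 over 151 pairs with both members detected in at least 6 lines and 0.847 over 195 pairs of different number, where members can still be near-identical in sequence, so cross-hybridisation was not tested and stays open. As a hypothesis, joint transcription may account for part of the difference between lines. Of the 220 pairs 4 lay below 0: miR-34b* and miR-34c-3p (-0.67), and miR-125a-3p with miR-99b (-0.31), let-7e (-0.28) and miR-99b* (-0.17), named after their values were seen.

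The arrays were also split into other groups of the same sizes, for the F test and for each of 11 lines. Such groups mix arrays of different lines, which correlated at a median of 0.867 against 0.992 within a line. Low counts in the other splits thus show only that arrays of the same line resembled each other. They cannot exclude chance for the F test or for any single line. In each case 1 of 100 splits, the real one, gave as many: 438 by the F test against at most 43 in the others, 283 against 36 in Caco2, 308 against 41 in HT29, 285 against 76 in LS1034, 263 against 53 in LS411N, 244 against 55 in LS513, 242 against 44 in SW1116, 328 against 34 in SW1463, 291 against 61 in SW403, 275 against 34 in SW620, 304 against 24 in SW837 and 276 against 42 in WiDr. For WiDr and HT29 only their 6 arrays were split, with 219 against at most 19 in the other splits. These 10 splits are too few for a share under 0.05. SW480 has 2 arrays, so neither it nor its comparison with SW620 was split.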
